A study of Mus musculus with 3 samples.

How the data were processed

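Gene expression was measured in single cells of mouse prefrontal cortex taken on postnatal day 6, after 1 exposure to about 3% sevoflurane. The labels give 3 libraries, all in 1 group, and no unexposed or differently dosed group; per the labels' protocols the mice were of both sexes, the tissue was flash frozen and RNA was taken with Trizol, a wording that does not describe how single cells were obtained, and the libraries were made with 10x Genomics Chromium chemistry and read on an Illumina NovaSeq. Per the submitters' processing notes CASAVA 1.8, Cell Ranger and Seurat were used, the last 2 without a version, with the genome build mm10. The deposited values are in natural log units: each is ln(1 + a whole number), since all 34958786 values above 0 became whole, within a tolerance of 1e-06, when the log was undone. Those whole numbers summed to between 4422 and 8135 per cell, a 1.84-fold range, while detected genes per cell ranged from 121 to 4213, a 34.8-fold range. They are therefore read as counts that the authors had corrected for depth, by a method not stated, and are called corrected counts. The depth before correction is unknown, no model for raw counts was fitted, and the authors' filters on cells and genes are not stated. Corrected counts summed to between 24612481 and 29581504 per library, with a median per cell of 5860.0, 5620.5 and 5558 in libraries 1, 2 and 3. Of 20368 genes, 20175 had a value above 0 in at least 1 cell.

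The planned comparisons, tests, gene lists, markers, rule for naming genes in the text and first set of alternatives were chosen before the data were examined. Suspected doublets were called in each library with Scrublet as provided in scanpy 1.11.5, and 120, 78 and 89 cells (2.51%, 1.52% and 2.08%) were removed, 287 in all, which left 13905. The 215 genes of the lists, of which 200 were in the table, were taken out of the 2000 most variable genes, so that 1956 genes defined the clusters. Cells were clustered with 30 principal components, 15 neighbours and the Leiden method at a resolution of 1.0 with seed 0, which gave 34 clusters. For each cluster the 50 genes with the largest fold over the other cells, with 10 CPM added to both, were compared with markers of 20 classes. A cluster took the name of a class with at least 3 markers among the 50 and more than any other class, unless another class had more among the first 10. That naming rule was set after a first clustering had been seen. Shares are means and SD of 3 libraries, with exact (Clopper-Pearson) 95% binomial intervals for single libraries, and a count of 0 allows a share of up to 3 counts of the total; both cover counting error only.

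For the comparisons each cell's corrected counts were scaled to CPM, the same total for every cell, cells of a class were averaged within each library, and log2(mean + 10 CPM) was fitted with limma 3.58.1 in R 4.3.3 with a mean-variance trend and library as a block. The added 10 CPM draws the fold of weakly expressed genes toward 0. The fit held 11 classes with at least 20 cells in each library and had 20 residual degrees of freedom; 9654 genes with a mean of at least 10 CPM over the class means were tested, 127 of them listed. Of those tested, 8381 were not used to define the clusters, so counts over all genes include some that were. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all genes tested, in either direction; the number past it when adjusted over the list alone is given beside it. Of 5 comparisons, 3 had been planned. Excitatory with inhibitory neurons and neurons with astrocytes were planned and not made, and migrating neuroblasts with astrocytes and oligodendrocytes with their precursors were added once the class sizes were known.

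The 16 lists were GABA-A, glycine, NMDA, and AMPA and kainate receptor subunits, tandem-pore potassium and HCN channels, cation-chloride cotransport, immediate early genes, apoptosis, heat shock proteins, unfolded protein response, mitochondrially encoded respiratory chain genes, synaptic genes, inflammatory signalling, iron handling with lipid peroxidation defence, tau and amyloid genes, and neurotrophin signalling. The 13 mitochondrially encoded genes were not analysed here, and neither were Gabra6, Glra4 and Neurog1 or genes of the Y chromosome. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over 55 tests; 12 passed, and with an estimated correlation 0 did, where 10 had an unadjusted p under 0.05. In 10 of the 55 the median, the mean and the direction of the test differed in sign, none of which passed: immediate early, apoptosis and synaptic genes in neuroblasts, cotransport and neurotrophin genes in endothelial cells, and cotransport, apoptosis, unfolded protein response, inflammatory and neurotrophin genes in oligodendrocyte precursors. In each comparison the text names from each list the 2 genes with the largest absolute log2 fold among those past the threshold that differed in the same direction in all 3 libraries, and always Slc12a2, Slc12a5, Gabra2 and Fos where tested; some genes that the rule takes are left out of the text and of the heat map, whatever their values, while counts include them. Genes outside that rule, such as Glrb where it did not pass and genes given as shares of cells, were named after their values were seen.

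Positions are those of GENCODE M21 for the build GRCm38, matched by gene symbol; the annotation release behind the deposited table is not given in the sources used here. The alternatives were a pseudocount of 1 or 50 CPM, no filter on low values, no library block, leaving out each library, a resolution of 2.0, clustering with the listed genes left in, doublets kept and an estimated correlation between the genes of a list. A fit of the compared classes alone, and log values centred on the median gene, were added after the data had been seen. The test was also tested on simulated data, in which astrocyte-like cells of each library were split at random and genes were changed by a known fold. Of genes raised 2-fold 86% passed, of those lowered 2-fold 55.1% and of those raised 1.5-fold 12%, with 0 calls among 9506 unchanged genes. Both parts came from 1 class, so they held no difference between classes that varies with the library. The 0 calls therefore do not give the error rate between real classes. Other tools were Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.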

Results

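The series holds the prefrontal cortex of mice on postnatal day 6, collected on the same day after 1 exposure to inhaled sevoflurane, a volatile general anaesthetic, at about 3%. Single cells were profiled by droplet RNA sequencing on the 10x Genomics Chromium platform in 3 libraries, which the labels give as replicates of 1 group. The labels name no unexposed group, so every comparison below is between cell classes within the exposed tissue, and no value measures a response to the anaesthetic. The labels do not say whether the 3 libraries came from separate animals. Each p-value is set against how class means varied between these libraries once each library's own shift was taken out. That spread is pooled over all 11 classes of the fit, small ones included, and may be technical. Library 1 held 4775 cells, library 2 held 5134 and library 3 held 4283, with 20368 genes. The deposited values were depth-corrected counts on a natural log scale, and they summed to 27887930, 29581504 and 24612481 corrected counts per library. A cell carried a median of 2603, 2502 and 2508 detected genes in libraries 1, 2 and 3.

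After removal of suspected doublets, 4655, 5056 and 4194 cells of libraries 1, 2 and 3 were clustered without any of the listed genes compared below, and 15 cell classes were named from fixed markers. Glia made up the largest classes among the cells recovered. Astrocyte-like cells, with Slc1a3, Slc1a2, Aldoc, Aqp4 and Gja1 among their markers, were 19.8% ± 2.39 of the cells (SD, n = 3 libraries). Oligodendrocyte precursor-like cells (Pdgfra, C1ql1, Lhfpl3, Matn4) were 15.6% ± 1.36, and oligodendrocyte-like cells (Bcas1, Enpp6, Mbp, Mag) were 3.07% ± 0.754. The larger oligodendrocyte-like cluster, 254 of 433 cells, had Bmp4, Neu4 and Gpr17 among its 10 leading genes. Neu4 was among the fixed markers of precursors, so part of this class may be cells early in differentiation. Migrating neuroblast-like cells, marked by Dlx6os1, Sp9, Dlx2 and Cd24a, were 12.8% ± 4.84; their share in libraries 1, 2 and 3 was 14.7%, 7.32% and 16.5%, with exact 95% binomial intervals of 13.7 to 15.7%, 6.62 to 8.07% and 15.3 to 17.6%. Microglia-like cells (P2ry12, Csf1r, Tmem119) were 9.93% ± 2.56, mural cell-like cells (Kcnj8, Vtn, Rgs5) 7.23% ± 2.35 and endothelial cell-like cells (Cldn5, Flt1, Pecam1) 6.38% ± 1.54. Intervals cover counting error only.

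Neurons past the migrating stage were few among the cells recovered. The preparation of single cells and the authors' filters on cells are not described, so shares may not reflect the tissue. The excitatory neuron-like cluster held 127 cells, a share of 0.864% ± 0.815, and its leading genes Neurod6, Tbr1 and Neurod2 stood beside Eomes, Neurod1 and Sstr2, which are markers of intermediate progenitors, the dividing precursors of excitatory neurons. Library 2 set that mean: without it the share was 0.416%. Cajal-Retzius cell-like cells, the Reln-producing cells of the outermost cortical layer, were 0.539% ± 0.137. No cluster was named inhibitory neuron-like, although Gad2 was among the 10 leading genes of the larger neuroblast cluster and Gad1 stood further down. The lack of an inhibitory neuron-like class thus rests in part on the naming rule. Since that class was missing and library 3 held fewer than 20 excitatory neuron-like cells, the planned comparisons of excitatory with inhibitory neurons and of neurons with astrocytes were not made. Blood-derived and border cells were also present: erythroid cell-like cells (hemoglobin genes, Alas2) were 2.38% ± 0.401, neutrophil-like cells (S100a8, S100a9, Ngp, beside the lymphocyte genes Igkc and Cd79a) 1.59% ± 1.16, though 0 at a cluster resolution of 2.0, fibroblast-like cells (Dcn, Col1a1) 0.601% ± 0.118, ependymal cell-like cells (Foxj1, Ccdc153) 0.642% ± 0.785 and border macrophage-like cells (Pf4, Lyve1, Mrc1) 0.491% ± 0.546. Library 3 set the shares of neutrophil-like and border macrophage-like cells, which were 0.928% and 0.176% without it, and library 1 set that of ependymal cell-like cells, 0.200% without it. The other 5 clusters, 10.7% ± 1.89 of the cells, met no naming rule. Their leading genes were Ttr, Sfrp1 and Igfbp5 (3.18% ± 1.10), Ccne2, Hells and Fignl1 (3.11% ± 0.409), Dct, Ptgds and Npy (1.798% ± 0.521), Helt and Hes6 (1.76% ± 0.948) and Spp1, Gpnmb and Igf1 (0.899% ± 1.09). Library 2 set the share of the Spp1, Gpnmb and Igf1 cluster, which was 0.580%, 2.12% and 0% in libraries 1, 2 and 3.

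**Figure D1:**
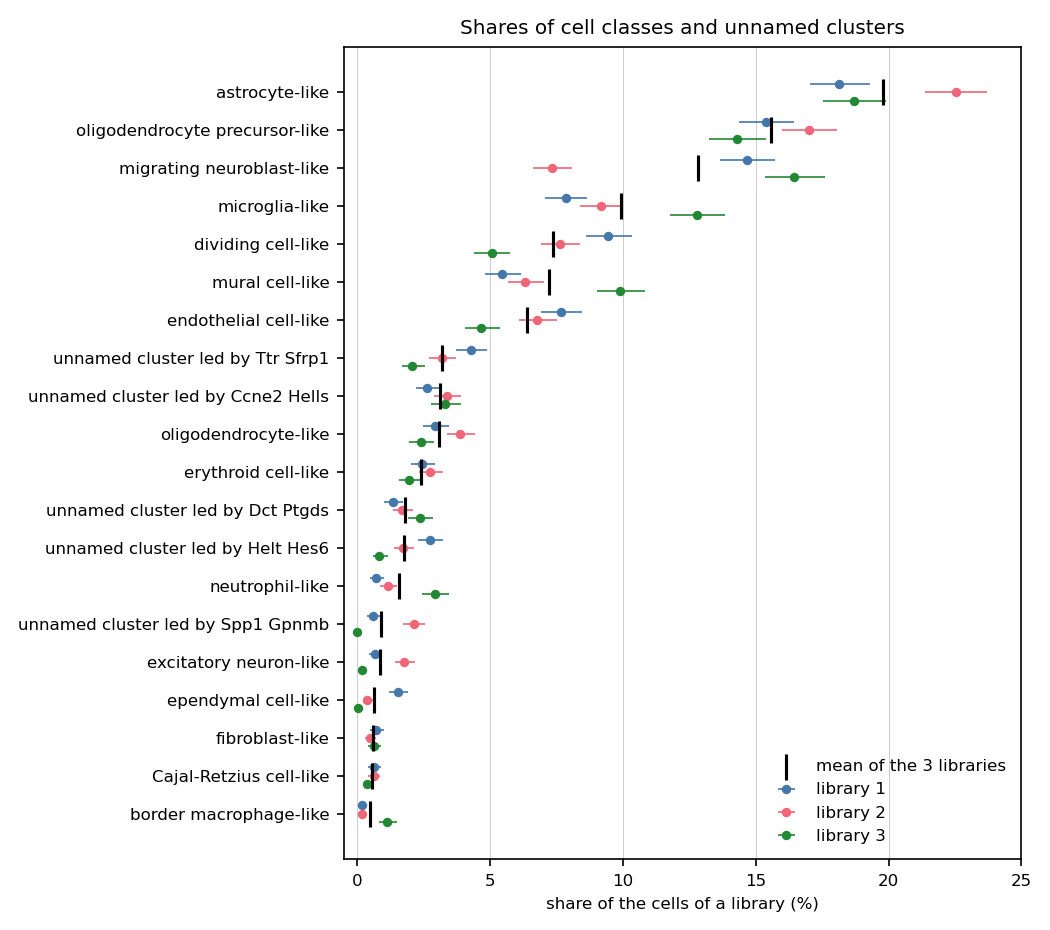
Share of the cells of each library (horizontal axis, percent) in each named class and unnamed cluster, with exact 95% binomial intervals as bars, a colour per library and a black mark at the mean of the 3 libraries. Astrocyte-like cells lie between 18.2% and 22.5%, whereas migrating neuroblast-like cells range from 7.32% in library 2 to 16.5% in library 3.

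Proliferating cells were recorded as the share in clusters named dividing cell-like, whose markers included Top2a, Ccnb1, Cenpf and Cenpe. They were 7.37% ± 2.21 of the cells (SD, n = 3), with 9.45% in library 1, 7.61% in library 2 and 5.05% in library 3, and exact 95% binomial intervals of 8.63 to 10.3%, 6.90 to 8.38% and 4.41 to 5.76%. The largest of their 4 clusters was led by histone genes together with Insm1, a factor of neuronal progenitors. Dividing cells also sat outside these clusters. Mki67 was among the 10 leading genes of the smaller microglia-like cluster. The cluster led by Ccne2, Hells and Fignl1 also had the DNA replication genes Lig1 and Mcm4 among its 10 leading genes. It stayed unnamed, with 2 precursor markers (Pdgfra, Lhfpl3) and 2 inhibitory neuron markers (Npas1, Nxph1). Npas1 and Nxph1 were also among the 10 leading genes of the larger precursor-like cluster. At a cluster resolution of 2.0 the dividing cell-like share was 4.97%.

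Red cell RNA was widespread. Hbb-bs, the adult beta-globin gene, was detected in 87.2% ± 8.46 of the cells outside the erythroid class (SD, n = 3), at 1732 ± 450.3 CPM (corrected counts scaled to the same total in every cell), against 402403 ± 13529.5 CPM in erythroid cell-like cells. Its level ranged over the other named classes from 224 ± 105 CPM in Cajal-Retzius cell-like cells to 7222 ± 1191 CPM in endothelial cell-like cells. The endothelial mean did not reflect more cells with the gene. Hbb-bs was in 73.8% ± 11.3 of endothelial cell-like cells, the lowest share of the named classes. Astrocyte-like cells had it in 87.7% ± 9.35, at 522 ± 189 CPM.

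Migrating neuroblasts were compared with astrocytes to ask how young neurons differ from the main glial class in the targets and reported responses of a volatile anaesthetic. This comparison was added once the neuron classes had proved too small, before the values of the listed genes were seen. Neuroblasts held far less of the GABA-A receptor subunits Gabrg1 and Gabrb1, and far more Cdk5r1, the p35 activator of the kinase Cdk5. Astrocytes are the reference in every comparison but the last. Gabrb1 and Slc7a11 were lower in each of those, and Gabrg1 in neuroblasts, microglia and endothelial cells. Such differences therefore do not single out 1 of the classes compared with astrocytes. Cdk5r1 (chromosome 11, 80477023 to 80481184) reached 346 ± 49.8 CPM in neuroblast-like cells and 5.37 ± 0.384 in astrocyte-like cells (SD, n = 3 libraries), a log2 fold of 4.52 ± 0.31 (SE; adjusted p = 1.60e-13). Gabrg1, the gamma-1 subunit (chromosome 5, 70751047 to 70842617), was at 4.42 ± 0.784 CPM against 229.9 ± 7.57, a log2 fold of −4.06 ± 0.19 (adjusted p = 8.89e-17).

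Of the 127 listed genes tested, 82 passed the threshold, 31 higher and 51 lower in neuroblasts, and 83 passed when adjusted over the list alone. Of all 9654 genes tested, 5633 passed. Among 4 GABA-A subunits, 1 was higher and 3 were lower, with Gabrb1 at a log2 fold of −3.77 and Gabra2 at −2.30. The NMDA receptor subunit Grin3a was lower (−2.14), and of 5 AMPA and kainate subunits 1 was higher and 3 were lower, including Gria3 (−0.87) and Gria2 (−0.70). The glycine receptor subunit Glrb did not pass (−0.26). Of 12 tandem-pore potassium and HCN channels 3 were tested, the potassium channels Kcnk1, Kcnk2 and Kcnk10, and no HCN channel. Kcnk1 (−3.57) and Kcnk2 (−1.54) were lower. In chloride cotransport 3 of 7 genes were lower, or 2 higher and 2 lower with log values centred on the median gene, led by Slc12a4 (−3.13) and Slc12a9 (−1.80), while Slc12a2, which carries chloride into immature neurons, did not pass (−0.26 ± 0.29 SE, adjusted p = 0.471).

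Of 11 heat shock genes 6 were higher and 1 was lower in neuroblasts, with Hsp90aa1 at a log2 fold of 2.15 and Hsp90ab1 at 1.48 (limma's camera test, adjusted p = 0.0170, and 0.303 with an estimated correlation). Of 12 unfolded protein response genes 8 were lower, among them Pdia4 (−1.78) and Hspa5 (−1.36), and 1 was higher, and the list's test did not pass (adjusted p = 0.161). Immediate early genes were split, 3 higher and 5 lower of 16, or 5 and 3 with log values centred on the median gene: Fos, a marker of recent activity, was lower (−2.87) and Jund higher (1.78). Apoptosis genes were split too, 5 higher and 4 lower of 16, with the survival gene Bcl2 lower (−2.57). Of 15 synaptic genes 5 were higher and 5 lower, with Nrxn3 higher (3.89). Tau and amyloid genes numbered 6 higher and 3 lower of 11, including the tau gene Mapt (1.59). Lower members outnumbered higher ones, with no list test past the threshold, in iron handling and lipid peroxidation defence (1 higher and 6 lower of 12, or 3 and 4 with centred values; Slc7a11, the cystine importer, −4.44, and Nfe2l2, −2.23), inflammatory signalling (1 and 4 of 8, or 3 and 3 with centred values; Il18, −2.95, Tnfrsf1a, −1.88) and neurotrophin signalling (1 and 3 of 5; Ntrk2, −3.19, Ntrk3, −2.53). The other 10 list tests did not pass, with adjusted p between 0.148 and 0.687. Centring the log values on the median gene moved the median of all genes from −0.15 to 0.24 and the split to 49 higher and 35 lower, and put Slc12a2 at a log2 fold of 0.13. The Gria2 call ended without library 2 (adjusted p = 0.0724), with a pseudocount of 1 CPM (0.221) and with centred values (0.157).

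Microglia, the resident immune cells, were set against astrocytes on the same lists. Their chemokines Ccl3 and Ccl4, the inducible chaperone Hspa1a and Slc12a2 were higher, and most of the receptor and synaptic genes tested were lower. Ccl3 (chromosome 11, 83647844 to 83649355) stood at 207 ± 32.6 CPM against 0.907 ± 0.217 in astrocyte-like cells (SD, n = 3), a log2 fold of 4.30 ± 0.15 (SE; adjusted p = 1.91e-20), and Ccl4 (chromosome 11, 83662584 to 83664683) at 177 ± 31.3 against 0.578 ± 0.503, a log2 fold of 4.13 ± 0.24 (adjusted p = 2.57e-15). Hspa1a was at 192 ± 88.8 CPM against 2.56 ± 0.410 (3.90 ± 0.26, adjusted p = 9.75e-14). Slc12a2 (chromosome 18, 57878678 to 57946821), a sodium, potassium and chloride importer, was at 73.7 ± 7.49 against 14.7 ± 1.16 (1.76 ± 0.29, adjusted p = 5.58e-06).

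In all 92 of 127 listed genes passed, 46 higher and 46 lower in microglia (94 when adjusted over the list alone), against 5890 of all 9654 genes tested. Of 18 inflammatory genes 8 were tested, 6 of them higher and 1 lower (limma's camera test, adjusted p = 4.97e-04, and 0.0762 with an estimated correlation). A gene could reach the minimum level for testing through microglia alone, so the group results of this comparison are not independent of that filter. Immediate early genes were higher in 10 of 16 with none lower, led by Ier5 (3.05) and Junb (2.69) (adjusted p = 0.00500, and 0.484 with an estimated correlation); Fos itself did not pass (−0.33 ± 0.40 SE, adjusted p = 0.513). Apoptosis genes were higher in 9 of 16 and lower in 3, with Casp8, the initiator caspase of death receptors, at 3.03 and Bid at 2.18. Heat shock genes counted 5 higher and 2 lower of 11, Hspa4 among the higher (0.73), and unfolded protein response genes 5 and 1 of 12, with Sdf2l1 higher (2.50) and Dnajb9 lower (−1.43). Cotransport genes counted 4 higher and 2 lower of 7; Slc12a4 (−2.37) and the kinase Stk39 (−2.07) were the lower members.

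Receptor genes of neural cells were lower. These were 3 of 4 GABA-A subunits (Gabrg1, −4.25, Gabrb1, −4.04, Gabra2, −2.84), Glrb (−2.07) and Grin3a (−2.38). All 5 AMPA and kainate subunits tested were lower, with Gria2 at −4.92 and Grik5 at −2.33 (camera test, adjusted p = 0.0405, and 0.251 with an estimated correlation). So were all 3 potassium channels tested, with Kcnk2 at −4.15 and Kcnk1 at −3.85. Synaptic genes were lower in 13 of 15, including Nrxn2 (−3.74), and higher in none (adjusted p = 4.97e-04, and 0.220 with an estimated correlation). Iron genes were balanced at 4 higher and 4 lower of 12, or 6 and 3 with values centred on the median gene: Slc40a1, the iron exporter, was higher (2.56) and Slc7a11 lower (−4.51). Tau and amyloid genes were higher in 2 of 11 and lower in 5 (Aplp1, −3.06, Mapt, −1.76), and neurotrophin genes higher in 1 of 5 and lower in 2 (Ntrk2, −4.57, Ntrk3, −3.06). Adjusted p for the other 7 list tests lay between 0.0839 and 0.642. Centred values moved the median of all genes from −0.25 to 0.08, the split to 59 higher and 39 lower, and the Fos log2 fold to 6.49e-04; with only the compared classes in the fit, Fos passed (adjusted p = 3.97e-04).

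Endothelial cells, which line the vessels, were set against astrocytes in the same way. They carried far more Klf2, a flow-responsive transcription factor, more of most immediate early genes tested, and more Slc40a1, and less of most receptor genes tested. Klf2 (chromosome 8, 72319033 to 72321656) was at 3465 ± 487 CPM against 13.8 ± 0.769 (SD, n = 3), a log2 fold of 7.18 ± 0.37 (SE; adjusted p = 1.55e-16), and its relative Klf4 at 503 ± 98.3 against 10.1 ± 2.45 (4.66 ± 0.43, adjusted p = 8.37e-11). Slc40a1 (chromosome 1, 45908068 to 45926523) reached 915 ± 21.8 CPM against 2.96 ± 1.11, a log2 fold of 6.16 ± 0.20 (adjusted p = 4.14e-21).

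Of 127 listed genes, 103 passed, 48 higher and 55 lower (105 when adjusted over the list alone), against 5727 of all 9654 genes tested. Of 24 immediate early genes 16 were tested, 15 of them higher (limma's camera test, adjusted p = 5.53e-07, and 0.251 with an estimated correlation). The 1 that did not pass was Fos (0.53 ± 0.40 SE, adjusted p = 0.267). Since a gene could reach the minimum level through endothelial cells alone, this group result is not independent of that filter. Inflammatory genes counted 5 higher and 1 lower of 8, with Nfkbia, an inhibitor of NF-kappa-B, higher (2.79) and Il18 lower (−4.38). Apoptosis genes counted 9 higher and 4 lower of 16, with Casp8 (3.17) and Bbc3 (2.13) higher. Heat shock genes were divided, 6 higher and 5 lower of 11: the small heat shock protein Hspb1 was higher (4.81) and the mitochondrial Hspe1 lower (−1.43). Iron genes were higher in 7 of 12 and lower in 3, Slc7a11 among the lower (−4.60). Unfolded protein response genes were lower in 6 of 12 and higher in 1 (Pdia4, −1.34; Sdf2l1, −1.03). App, the amyloid precursor gene, was higher (2.23) and Aplp1 lower (−3.65), within 2 higher and 5 lower of 11 tau and amyloid genes, and Igf1r was higher (3.40) and Ntrk2 lower (−5.22), within 1 and 2 of 5 neurotrophin genes.

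Lower in endothelial cells were 3 of 4 GABA-A subunits, among them Gabrg1 (−4.50), Gabrb1 (−3.86) and Gabra2 (−2.94), and the single tested members of the glycine and NMDA lists, Glrb (−2.10) and Grin3a (−2.30). All 5 AMPA and kainate subunits tested were lower, Gria2 (−5.41) and Grik5 (−2.43) by the most (camera test, adjusted p = 0.0170, and 0.220 with an estimated correlation). So were the 3 potassium channels tested, such as Kcnk2 (−4.37) and Kcnk1 (−4.00). Synaptic genes were lower in 13 of 15 and higher in 1, with Nrxn2 at −4.08 (adjusted p = 4.97e-04, and 0.220 with an estimated correlation). Cotransport genes counted 1 higher and 3 lower of 7, or 3 and 3 with centred values, with Slc12a4 at −2.77 and Slc12a9 at −2.13. The remaining 8 list tests had adjusted p between 0.0987 and 0.669. Slc12a2 did not pass (0.58 ± 0.29 SE, adjusted p = 0.0892) but did so without library 3 (0.0280), with doublets kept (0.0213), with centred values (0.0246) and with only the compared classes in the fit (8.13e-04), where Fos (5.50e-04) passed too. Centred values moved the median of all genes from −0.11 to 0.08.

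**Figure D2:**
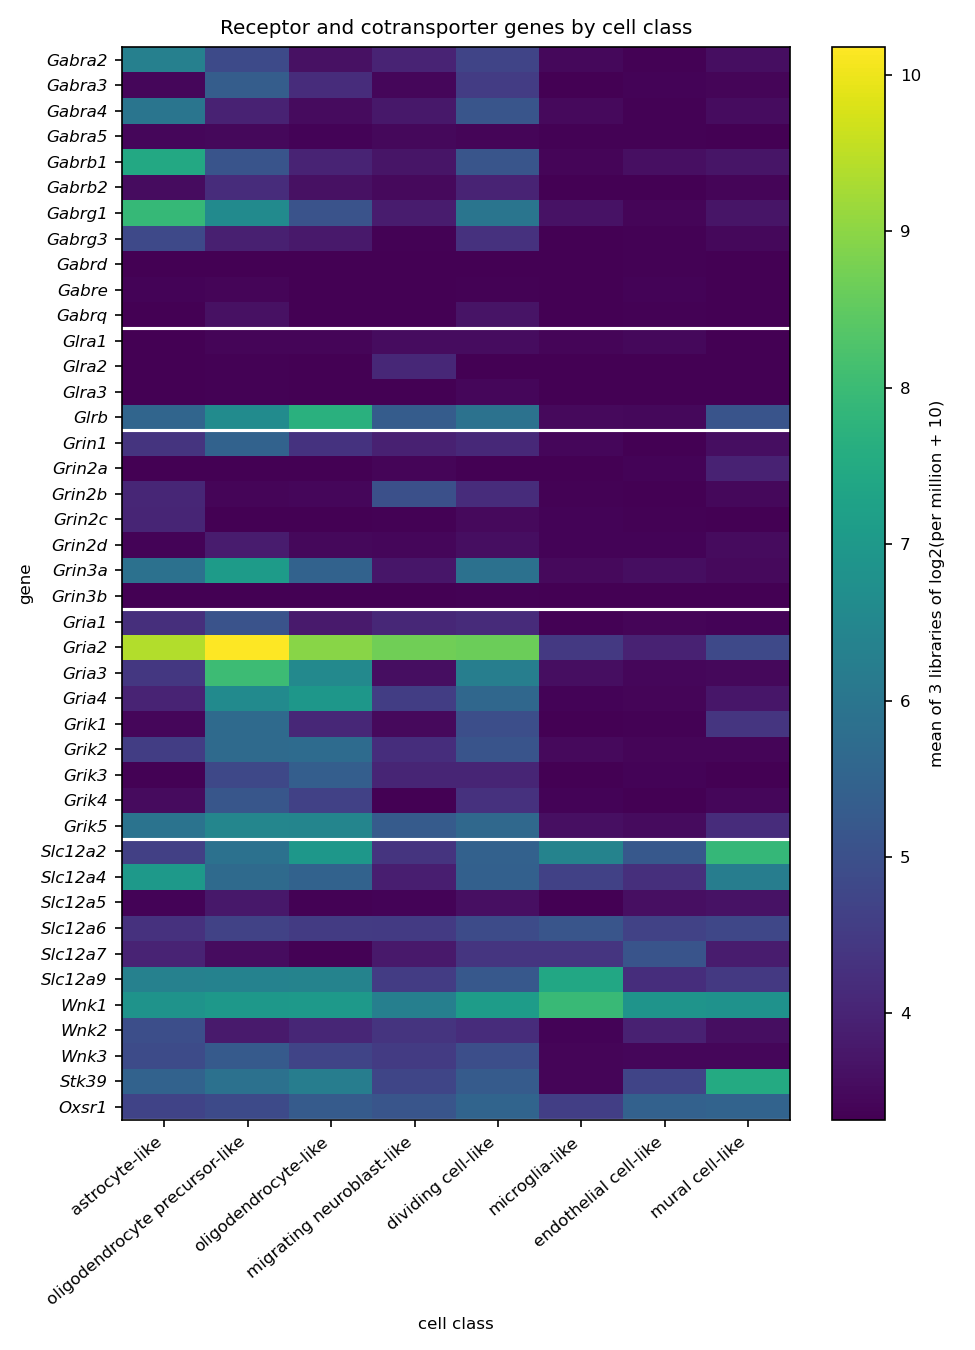
Mean over 3 libraries of log2(CPM + 10) for genes (rows) of the receptor and chloride cotransport lists in 8 cell classes (columns), with white lines between lists and colour as the scale. Gria2 is the brightest row, at 1149 CPM in oligodendrocyte precursor-like cells, while microglia-like and endothelial cell-like columns are dark for nearly every receptor gene.

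Oligodendrocyte precursors, which divide and give rise to myelinating cells, were compared with astrocytes. Precursors held more AMPA receptor genes, more of the immediate early gene Egr1 and less of the GABA-A subunit Gabrb1. Egr1 (chromosome 18, 34859823 to 34864984) was at 294 ± 30.96 CPM against 26.0 ± 3.62 in astrocyte-like cells (SD, n = 3), a log2 fold of 3.08 ± 0.25 (SE; adjusted p = 2.29e-11). Gria3 (chromosome X, 41400854 to 41678601) was at 250.4 ± 8.32 against 11.9 ± 2.83 (3.58 ± 0.19, adjusted p = 7.76e-16) and Gabrb1 at 24.5 ± 2.44 against 168 ± 15.3 (−2.36 ± 0.22, adjusted p = 2.00e-10). Slc7a11 (chromosome 3, 49892526 to 50443614) was lower by a log2 fold of −4.35 ± 0.31 (adjusted p = 8.28e-13).

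Here 67 of 127 listed genes passed, 41 higher and 26 lower in precursors (67 when adjusted over the list alone), and 110, of which 71 were higher and 39 lower among 122 tested, when only the 2 compared classes entered the fit. Of all 9654 genes tested 3657 passed. Of 9 AMPA and kainate subunits 5 were tested, all of them higher, Gria4 (2.58) next to Gria3 (limma's camera test, adjusted p = 0.00223, and 0.220 with an estimated correlation). Grin3a (1.23) and Glrb (1.06) were higher too. Of 4 GABA-A subunits 1 was higher and 3 were lower, Gabra2 included (−1.45). Of 23 synaptic genes 15 were tested, 10 of them higher and none lower. Snap25, the vesicle fusion gene, was at 2.63 and Shank1 at 1.89 (camera test of the list, adjusted p = 0.00144, and 0.220 with an estimated correlation). Since a gene could reach the minimum level through precursors alone, neither group result is independent of that filter. Kcnk10 was higher (1.09) and Kcnk1 lower (−0.94), within 1 higher and 2 lower of 3 channels. In cotransport Slc12a2 was higher (1.27) and Slc12a4 lower (−1.31), and the other 5 of 7 did not pass.

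Immediate early genes counted 3 higher and 4 lower of 16, with Nr4a1 higher (1.94) and Fos lower (−1.23). Heat shock genes were higher in 6 of 11 with none lower (Hsph1, 1.04; Hsp90aa1, 0.95), and tau and amyloid genes in 4 of 11 with none lower (Cdk5r1, 1.60; Mapt, 1.36). Apoptosis genes counted 3 higher and 3 lower of 16, with Bcl2 (−1.83) and Bcl2l1 (−0.76), which protect cells from death, both lower. Unfolded protein response genes counted 2 higher and 4 lower of 12 (Sdf2l1, 1.64; Dnajb9, −0.84), iron genes 2 and 5 of 12 (Nfe2l2, −2.46), inflammatory genes 0 and 2 of 8 (Nfkbia, −2.03; Il18, −0.85) and neurotrophin genes 1 and 2 of 5 (Sort1, −1.25; Ntrk2, −0.84). Adjusted p of the other 9 list tests ranged from 0.106 to 0.988. The calls of Ntrk2 and Fos ended without library 2 (adjusted p = 0.0636 and 0.0897) and without library 3 (0.0984 and 0.0593), and with a pseudocount of 1 CPM (0.328 and 0.113). That pseudocount also ended those of Glrb (0.0885), Grin3a (0.173), Kcnk1 (0.194) and Gabra2 (0.0942).

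The last comparison followed the oligodendrocyte lineage from precursors to oligodendrocytes, and it too was added after the class sizes were seen and before the values of the listed genes were. Of the 433 oligodendrocyte-like cells, 254 came from the cluster with the precursor marker Neu4 among its 10 leading genes. Oligodendrocytes held less Egr1, less of the tested GABA-A subunits and of most synaptic genes tested, and more Slc12a2 and Aplp1. Egr1 was at 5.40 ± 3.85 CPM in oligodendrocyte-like cells and 294 ± 30.96 in precursor-like cells (SD, n = 3), a log2 fold of −4.33 ± 0.25 (SE; adjusted p = 2.49e-14). Slc12a2 was at 114 ± 17.1 against 49.4 ± 4.22 (1.06 ± 0.29, adjusted p = 0.00583) and Aplp1 at 874 ± 220.4 against 298 ± 19.7 (1.5 ± 0.21, adjusted p = 1.81e-06).

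The threshold was passed by 54 of 127 listed genes, 18 higher and 36 lower in oligodendrocytes (56 when adjusted over the list alone), and by 2793 of all 9654 genes tested. Immediate early genes were lower in 9 of 16 and higher in none, Fos included (−2.41) (adjusted p = 4.97e-04, and 0.390 with an estimated correlation). Synaptic genes were lower in 10 of 15 and higher in 1 (Snap25, −1.98; Nrxn3, −1.95; adjusted p = 4.97e-04, and 0.220 with an estimated correlation). All 4 GABA-A subunits tested were lower, with Gabrg1 at −1.53 and Gabra2 at −1.23, and so were Grin3a (−1.61), Gria3 (−1.48) and Gria2 (−1.22), 2 of 5 AMPA and kainate subunits, and the 3 channels (Kcnk1, −1.91; Kcnk2, −1.85). Glrb was higher (1.03). Neurotrophin genes were lower in 2 of 5 (Ntrk2, −2.12; Ntrk3, −1.75) and inflammatory genes in 4 of 8 (Tnfrsf1a, −1.06; Nfkbia, −0.88).

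Slc12a2 was the 1 cotransport gene of 7 that passed. Tau and amyloid genes were higher in 5 of 11 and lower in none, Mapt among them (1.02), heat shock genes in 5 of 11 (Hspe1, 0.65; Hspa4, 0.58) and unfolded protein response genes in 2 of 12 (Sdf2l1, 0.95; Eif2ak3, 0.51). Apoptosis genes counted 3 higher and 1 lower of 16, the lower being Bcl2 (−2.02), and none of 12 iron genes passed. Adjusted p in the other 9 list tests lay between 0.121 and 0.833. Calls that ended without library 2 were those of Slc12a2 (adjusted p = 0.104), Mapt (0.0641) and Eif2ak3 (0.0524), without library 3 those of Eif2ak3 (0.276), Glrb (0.0588), Hspa4 (0.05004) and Nfkbia (0.0986), and without library 1 that of Nfkbia (0.0765). A pseudocount of 1 CPM ended those of Slc12a2 (0.0819), Mapt (0.234), Eif2ak3 (0.395), Glrb (0.170), Grin3a (0.0703) and Gria2 (0.0701), and doublets kept ended that of Eif2ak3 (0.0750).

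Immediate early genes were also read as the share of cells with at least 1 corrected count, since the labels date the tissue to the day of exposure. The labels name no unexposed group and do not describe how single cells were obtained. These shares therefore cannot tell exposure from the handling of tissue and cells. Fos (chromosome 12, 85473890 to 85477273) was in 88.5% ± 12 of ependymal cell-like and 70.6% ± 4.18 of border macrophage-like cells (SD, n = 3), both small classes, of which the former held 1 cell in library 3. Among the larger named classes it was in 60.5% ± 5.16 of endothelial cell-like cells, followed by microglia-like cells at 32.3% ± 3.76, astrocyte-like cells at 25.1% ± 3.88 and oligodendrocyte precursor-like cells at 21.4% ± 2.93. Among further small classes, fibroblast-like cells stood at 36.6% ± 8.41, Cajal-Retzius cell-like cells at 28.3% ± 3.68 and excitatory neuron-like cells at 6.63% ± 7.20. Among unnamed clusters that led by Ttr, Sfrp1 and Igfbp5 stood at 47.5% ± 14.4 and that led by Spp1, Gpnmb and Igf1 at 28.8% ± 1.13 (n = 2 libraries). That led by Ccne2, Hells and Fignl1 stood at 25.2% ± 6.198, that led by Helt and Hes6 at 23.8% ± 6.42 and that led by Dct, Ptgds and Npy at 21.2% ± 6.88. Dividing cell-like cells stood at 16.7% ± 5.63 and mural cell-like cells at 15.3% ± 1.09. In erythroid cell-like cells, taken as the background of free RNA, the share was 5.68% ± 3.33 at a median of 282 genes per cell, so that 3.85% ± 1.31 in neuroblast-like cells (median of 1722 genes) and 1.86% ± 2.41 in oligodendrocyte-like cells (median of 2999) lay at or below background as means, while in library 2 they were 2.97% and 4.59% against 2.16%; the mean of oligodendrocyte-like cells was 0.50% without library 2. Egr1 followed another order, with 63.0% ± 3.91 of oligodendrocyte precursor-like cells, 28.5% ± 1.58 of dividing cell-like cells and 10.5% ± 1.45 of astrocyte-like cells, against 7.49% ± 1.68 of erythroid cell-like cells. Klf2 was in 98.9% ± 0.755 of endothelial cell-like cells and 5.96% ± 1.99 of erythroid cell-like cells. Npas4, which neurons induce on calcium entry, was in 0 of 335 erythroid cell-like cells, in 0.101% ± 0.0168 of all cells, in 9.62% ± 8.11 of Cajal-Retzius cell-like cells and in 3.98% ± 5.71 of ependymal cell-like cells, with 6.90%, 3.23% and 18.8% in libraries 1, 2 and 3 of the former and 1.41%, 10.5% and 0% of the latter, whose libraries 2 and 3 held 19 and 1 cells. Differences between classes in these shares were not tested.

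**Figure D3:**
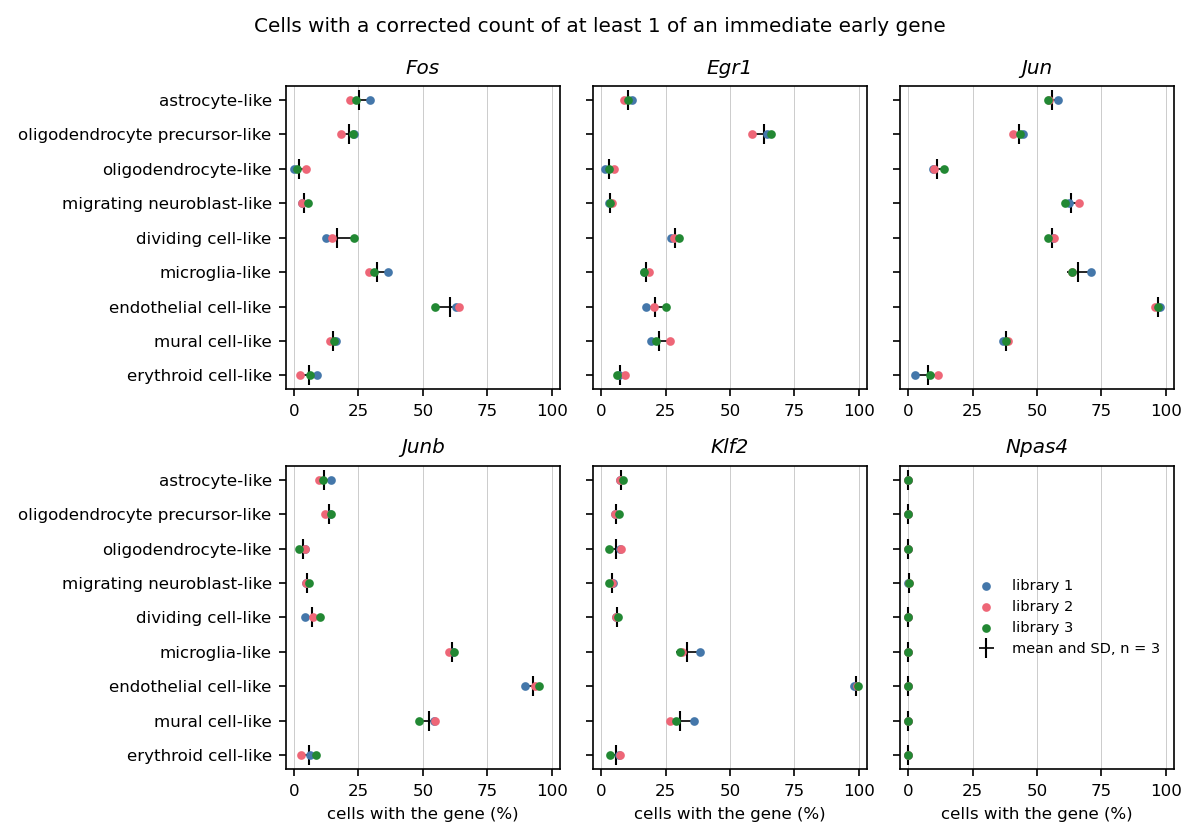
Share of cells (horizontal axis, percent) with a corrected count of at least 1 of each of 6 immediate early genes in 9 cell classes, with a point per library and the mean and SD of 3 libraries in black. Fos lies at 60.5% in endothelial cell-like cells and 5.68% in erythroid cell-like cells, and Npas4 is near 0 in each of the 9 classes.

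The chloride cotransporter Slc12a5, which exports chloride from mature neurons (chromosome 2, 164960802 to 164999731), was below the minimum level for testing. It was detected in 0.900% ± 0.120 of all cells. The cluster led by Ccne2, Hells and Fignl1, which held precursor markers, stood at 5.30% ± 0.440 and oligodendrocyte precursor-like cells at 1.85% ± 0.163. The share of Cajal-Retzius cell-like cells was 6.90%, 0% and 0% in libraries 1, 2 and 3. Of 335 erythroid cell-like cells 0 had it, which allows a share of up to 0.896% for counting error only, at a median of 282 genes per cell. Slc12a2 was in 64.9% ± 4.77 of mural cell-like cells, 43.4% ± 4.20 of oligodendrocyte-like cells and 1.29% ± 1.23 of erythroid cell-like cells.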

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

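The fits limited to the compared classes and the centred values were alternatives chosen after the data had been seen. Of the values of single genes under all alternatives, 1756 kept both direction and side of the threshold, 28 lost their call, 8 gained one, of which 2 belong to genes left out of the text, and 2 changed direction; the latter, both with centred values, were Slc12a2 in neuroblasts (log2 fold of 0.13) and Fos in microglia (0.00065), neither past the threshold before or after. Each lost call is given in the account of its comparison with every alternative that put its adjusted p above the threshold; 13 of the 28 were with a pseudocount of 1 CPM. Without each library in turn the listed genes past the threshold were 71 to 76 for neuroblasts, 86 to 87 for microglia, 88 to 95 for endothelial cells, 55 to 57 for oligodendrocyte precursors and 40 to 46 for oligodendrocytes, and 11 to 12 list tests passed. Without the library block they were 82, 92, 103, 65 and 54. For precursors the number was 110 with only the compared classes in the fit, against 67; the cause was not tested. With an estimated correlation 0 list tests passed, against 12. Every list that had passed had an estimate above the preset 0.01, so the 12 calls rest on the preset value. The estimates were 0.470 for immediate early, 0.190 for heat shock, 0.147 for AMPA and kainate, 0.143 for synaptic and 0.0395 for inflammatory genes. At a cluster resolution of 2.0, which divides and renames clusters, the share of oligodendrocyte precursor-like cells was 17.5%, that of dividing cells 4.97% and that of neutrophil-like cells 0. A test on counts of reads was not run, because corrected counts are not reads, and the alternatives of the planned comparisons of neurons were not run, since those comparisons were not made. The depth before correction is unknown. On data simulated from astrocyte-like cells, the largest class, 12% of 1.5-fold gains passed, so smaller gains would mostly be missed there. Recovery in the other classes was not simulated.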

Other observations

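Several classes that entered no comparison are given here as values with no test. In Cajal-Retzius cell-like cells Snap25 was in 100% ± 0 of them (SD, n = 3) and Syt1, the calcium sensor of vesicle release, in 98.9% ± 1.86, against 2.99% ± 1.21 and 1.11% ± 1.24 of erythroid cell-like cells, taken as background (median of 3319.5 and 282 genes per cell). Excitatory neuron-like cells had Gria2 in 82.1% ± 6.89 and the NMDA subunit Grin2b in 29.97% ± 4.97, against 16.1% ± 8.22 and 0.292% ± 0.506 in erythroid cell-like cells, whereas Grin2b was in 2.22% ± 1.93 of Cajal-Retzius cell-like cells. Mural cell-like cells, the contractile and supporting cells of vessels, held Slc12a2 at 226 ± 21.8 CPM.

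The cluster led by Spp1, Gpnmb and Igf1, genes of phagocytic microglia, also held Lag3, Itgax and Lyz2 among its leading genes. The chemokine gene Ccl3 was in 54.9% ± 0.955 of its cells (SD, n = 2 libraries with such cells), against 36.2% ± 3.08 of microglia-like cells and 1.35% ± 0.951 of erythroid cell-like cells. The level of Ccl3 was 194 ± 37 CPM in the cluster and 207 ± 32.6 CPM in microglia-like cells. Ccl4 went the other way, in 14.0% ± 4.04 of the cluster's cells and 20.7% ± 2.94 of microglia-like cells. The cluster led by Dct, Ptgds and Npy held Mlana and Pmel, genes of pigment cells, beside Fabp7 and Aldh1l1 of astrocytes. That led by Helt and Hes6 held Dll1, a Notch ligand of neural progenitors.

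Tests of the amount of white matter, of ventricular wall tissue, of a general gain of dividing cells and of female cells, in the paragraphs that follow, were chosen only after the result was seen; those of misplaced cells, of free Xist RNA and of other splits were set before. The Spp1 and Gpnmb cluster held 27, 107 and 0 cells of libraries 1, 2 and 3, where 0 of 4194 cells allows a share of up to 0.0715%. Placement of such cells of library 3 among microglia-like cells is argued against, because cells with both genes were 4.85%, 16.0% and 0.187% of the 2 groups together, a ratio of library 3 to library 1 of 0.0385. Different amounts of white matter remain a candidate explanation: the oligodendrocyte-like share was 3.88% in library 2, 2.94% in library 1 and 2.38% in library 3, the same order, but 3 libraries are too few to decide. No biological explanation was tested, since the labels give 1 group.

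Ependymal cell-like cells, which line the ventricles, were 1.53%, 0.376% and 0.0238% of libraries 1, 2 and 3. Uneven amounts of ventricular wall tissue may account for this, and 4 of 5 clusters with progenitor or neuroblast genes ranked the libraries in the same order, such as that of histone genes with Insm1 at 6.68%, 3.62% and 2.05%; the Synpr and Dlx6os1 cluster broke it at 8.44%, 3.88% and 14.1%. The first form of that test held 4 clusters, all in that order, and the fifth was added because those 4 had been picked for the pattern, so it remains open. A general gain of dividing cells in library 1 would raise the other dividing cell-like clusters there. These were 2.77% of library 1 (interval of 2.32 to 3.28%), 3.995% of library 2 and 3.00% of library 3. The values argue against such a gain, though the interval covers counting error only and library 3 lies inside it. No biological explanation was tested.

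Xist, the RNA that silences an X chromosome in female cells, was in 99.6%, 99.0% and 98.6% of astrocyte-like cells of libraries 1, 2 and 3, although the labels' protocol speaks of mice of both sexes. To test free Xist RNA in the droplets as the source, erythroid cell-like cells were used. Their share was at most 0.385 times that in astrocyte-like cells of the same library, below the limit set beforehand. They had a median of 282 genes per cell against 2785 in astrocyte-like cells. A lower share could follow from that alone, so the test cannot decide and free Xist RNA stays open. Whether cells of female animals made up nearly all of each library stays open: the lowest of the 3 shares, 98.6%, is the observation itself and no separate test of it. The Y-linked genes that would decide it were not analysed here, and the protocol wording may cover the whole study and not these 3 libraries.

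Other splits of the 6 class means of each comparison number 10 with the real one, too few for a share under 0.05. The real split gave 82 listed genes for neuroblasts, 92 for microglia, 103 for endothelial cells, 67 for oligodendrocyte precursors and 54 for oligodendrocytes, in each case 1 of the 10, and the highest of the others was 0 in all 5 comparisons. Every other split puts both classes on both sides, so low counts there were built in. No conclusion is drawn from them.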
